A study of Mus musculus with 6 samples.

How the data were processed

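RNA from cultured cells of mouse embryonic stomach, intestine and Barx1 intestine was measured on 6 Affymetrix arrays, 2 per group, with 22690 probe sets. The values are log2 expression values that the authors deposited, summarised by RMA per the submitters' processing notes; the version and implementation of RMA are not given in the sources used here. RMA corrects background, brings the arrays to a common distribution and combines the probes of each probe set, so differences that affect most genes alike would be removed before deposit. That the scale is log2 was read from the values, which run from 2.48 to 14.7 with medians of 6.93 to 6.98. Depth has no counterpart on an array, and the number of arrays limits the precision. The groups and replicate numbers were taken from the labels, which call the samples biological replicates.

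Gene names came from the platform annotation. Of the probe sets 20380 named 1 gene, 691 several and 1606 none, and 64 were spiked or quality controls. The 1606 include controls, and 1555 remain without them. A further 13 controls were named by the annotation. Control probe sets and those without a single gene name were left out of the gene tests. Identifiers of 20351 probe sets matched the reference gene table, and 0 symbols had to be updated. Each of the 12393 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 4956 genes with more than 1. No named gene had another probe set called in the opposite direction.

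All 6 arrays entered a single fit of 3 group means with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8) for reading, leaving 3 residual degrees of freedom and a prior of 2.58. P-values were adjusted by the Benjamini-Hochberg method over all genes within each comparison, and a gene passed at an adjusted p under 0.05. Every adjusted p printed for a gene comes from this limma fit. SE is that of the moderated fit and SD is that of the 2 arrays. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. With an estimated correlation 0 lists passed in any comparison, against 7, 8 and 9 at the preset value, and fry called 4, 2 and 6.

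The 28 lists were fixed before the data were examined. They cover smooth muscle contractile genes, stomach and pylorus regulators, intestine mesenchyme regulators, Hox genes in 2 groups, secreted Wnt antagonists, Wnt targets, Hedgehog response, BMP signalling, extracellular matrix, cartilage and tendon, interstitial cells of Cajal, enteric neurons and glia, endoderm epithelium, intestinal epithelium, mesothelium, endothelium, leukocytes, erythroid cells, spleen primordium, pancreas, liver, skeletal muscle, cell cycle, immediate early genes, glycolysis and hypoxia, interferon response and sex-linked genes. Lists with under 5 measured members received no test, which applied to the sex-linked list. Also fixed beforehand were the comparisons, the tests and the rule for naming genes. That rule names Barx1 and Nkx3-2, the 10 largest differences in each direction among genes past the threshold with non-overlapping arrays, up to 4 members of each list with the smallest p, and the 10 largest among genes called in both comparisons with intestine. Predicted genes and those without an approved-style symbol were passed over. A gene that the rule names in one comparison may be given in another, and genes outside the rule are marked where they appear.

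For the overlap of the comparisons that share the intestine arrays, 100 sets of unchanged groups were simulated. Each gene had 1 mean for all groups and normal noise at its moderated SD from the limma fit. The fit was tested on simulated data for the comparison of Barx1 intestine with intestine, over 12393 genes in 5 simulations with 200 changed genes. It recovered 89.4% of genes changed by a log2 of 1 and 98.6% of those changed by 2, and 3.57% of its calls were false. A comparison without changes gave at most 1 call. In all these simulations the genes varied independently of each other, with the same spread in every group. In the 5 simulations of the fit, the spread of each gene was drawn from the prior that limma had fitted. Those 5 therefore tried the fit on data made by its own assumptions. The real replicates differed in spread (SD of the difference 0.149 in stomach, 0.232 in intestine and 0.199 in Barx1 intestine). The simulated rates may therefore not hold for the real arrays. Alternatives covered a filter on dim genes, median centring, a second quantile normalisation, the mean of all probe sets, a variance trend, a fit of 2 groups, the replicate number as a block, leaving out each array, other thresholds, other list tests and split controls. Crossed replicate numbers, and the mean levels of the epithelial and leukocyte lists as covariates, were added after seeing the data. A setting for linear values was not run, since the values are on a log scale. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.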

Results

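Gene expression was profiled on 6 Affymetrix 3′ arrays, each hybridised with RNA from cells of embryonic day 13.5 mouse gut that had been dissociated with proteases to reduce the endoderm and then kept in culture for 3 days with 20% serum. The arrays fell into 3 groups of 2 biological replicates: stomach cells, intestine cells, and intestine cells of embryos in which Bapx1-Cre switched on Barx1 from the Rosa26 locus (called Barx1 intestine here). The stomach and intestine control embryos carried either the Cre or the Rosa26 allele alone. BARX1 is a homeodomain transcription factor of the embryonic stomach mesenchyme, and the title of the series asks how it controls stomach smooth muscle development. The array medians lay between 6.93 and 6.98 on the log2 scale, and 12393 genes were measured. The number of arrays limits the precision of every value. A level near or below the lower quartile of an array (4.72 to 4.76) was not shown to be above background, and a difference from such a level is read as a lower bound on its size. The SD over genes of the difference between replicates was 0.149 for the stomach, 0.232 for the intestine and 0.199 for the Barx1 intestine, against 0.295 to 0.420 between arrays of different groups.

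Barx1 itself was read first in every sample. Its log2 level was 9.81 ± 0.02 in stomach, 5.03 ± 0.15 in intestine and 8.72 ± 0.10 in Barx1 intestine (SD, n = 2 each). The stomach exceeded the intestine by 4.78 (SE 0.09, adjusted p = 0.000114), and the Barx1 intestine exceeded the intestine by 3.69 (SE 0.09, adjusted p = 0.000207). The intestine level lay near the lower quartile of its arrays (4.73 and 4.72) and was not shown to be above background, so both differences from it are read as lower bounds. The level in Barx1 intestine stayed below that of the stomach (difference -1.08, adjusted p = 0.0120). The order of the groups followed the labels, and no value here separates transcripts of the transgene from those of endogenous Barx1. Nkx3-2, also called Bapx1, the locus that carries the Cre, read 5.01, 4.75 and 4.97, and none of its differences passed the test (adjusted p from 0.198 to 0.870).

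**Figure D1:**
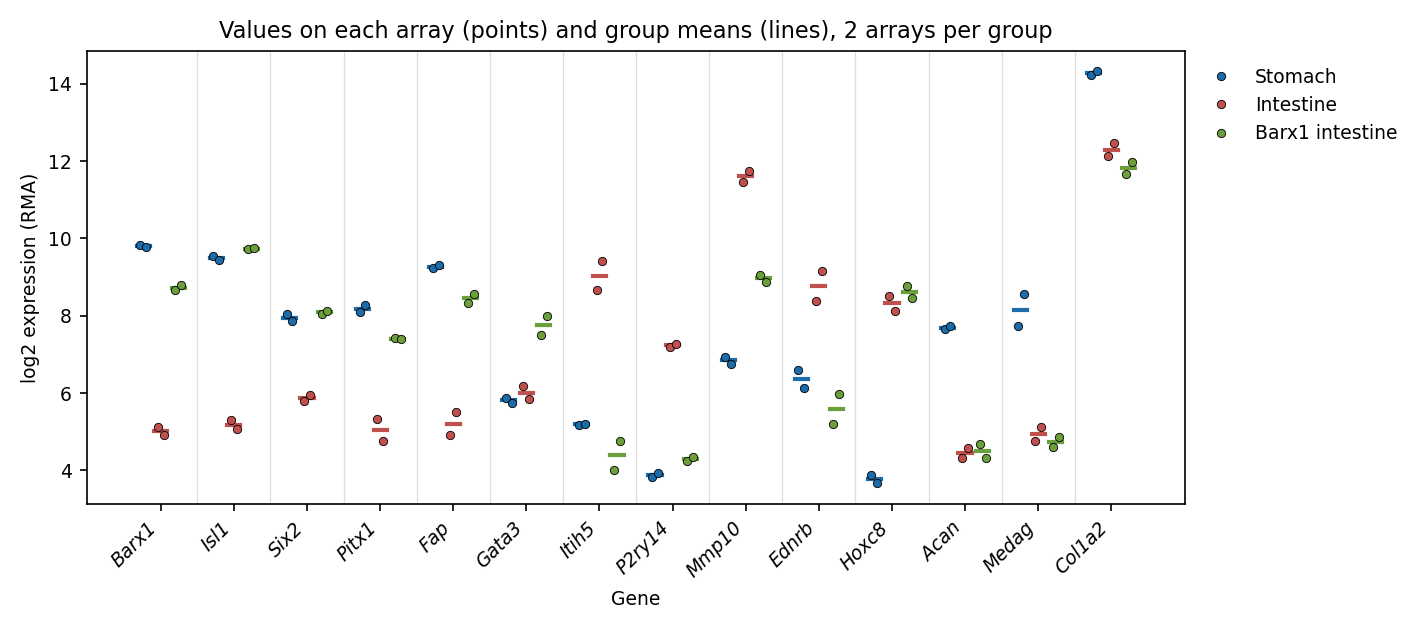
Log2 expression of 14 named genes on each of the 6 arrays. Points are single arrays and lines are group means of 2 arrays; Barx1 reads 9.81 in stomach, 5.03 in intestine and 8.72 in Barx1 intestine.

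The comparison of stomach with intestine describes the regional identity of the control cultures. After Barx1, the genes with the largest excess in stomach included Isl1, a LIM-homeodomain factor (log2 difference 4.31, SE 0.10), Mgp, an inhibitor of mineralisation in the matrix (4.31), Fap, a fibroblast surface protease (4.07), and the homeobox genes Prrx1 (3.76) and Pitx1 (3.13). The orphan nuclear receptor gene Nr2f1 (3.22), the proteoglycan gene Acan (3.24) and Medag (3.20) were also higher. Genes with a large excess in intestine included Mmp10, a matrix metalloproteinase (stomach 6.84 ± 0.14, intestine 11.61 ± 0.21, difference -4.76), the Hox gene Hoxc8 (-4.55), Itih5 (-3.84), the nucleotide-sugar receptor gene P2ry14 (-3.36), Mmp13 (-3.33) and Aldh1a3, an enzyme of retinoic acid synthesis (-3.02). Each group was measured on 2 arrays, every difference above had an adjusted p of 0.00428 or less, and each stayed past the threshold in all 6 fits that left out 1 array.

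Of the 14 measured regulators of stomach and pylorus mesenchyme, 8 rose in stomach and 0 fell, and 8 passed when adjusted over the list alone. Besides Barx1 and Isl1 they included Six2 (2.09), a homeobox gene of the pylorus, and Osr1 (1.14). The list stood higher than other genes (adjusted p = 0.000429 by camera, and adjusted p = 0.806 with an estimated correlation). The spleen primordium list, whose tissue lies beside the stomach, had 5 of 7 members higher, also 5 when adjusted over the list alone, among them Tlx1 (1.35), which spleen formation needs, and Wt1 (1.33), Nkx2-5 (1.02) and Nr2f2 (0.94). The fifth, Tcf21 (0.51), lay outside the naming rule here and was chosen after its values were seen, and 5 of the 7 genes also stand in other lists (adjusted p = 0.000712 by camera, and adjusted p = 0.463 with an estimated correlation). Extracellular matrix genes had 10 members higher and 1 lower of 25 (13 and 1 adjusted over the list alone), with Col1a2 (1.98), Fbln5 (1.55), Loxl1 (1.04) and Bgn (0.76) as examples; the lower gene, chosen after its values were seen, was Postn (-0.66) (adjusted p = 0.000831 by camera, and adjusted p = 0.891 with an estimated correlation). Cell cycle genes had 17 of 25 higher and 0 lower, 17 adjusted over the list alone, such as Ccna2 (0.81), Cenpf (0.82) and Kif11 (0.80) (adjusted p = 6.81e-08 by camera, and adjusted p = 0.463 with an estimated correlation).

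Lists of other cell types moved in the same comparison. The endoderm epithelium list was lower in stomach, with a median of -1.17 over 22 genes, 2 of them past the threshold, namely Spint1 (-1.39) and Foxa1 (-2.71), and 1 adjusted over the list alone (adjusted p = 0.00228 by camera, and adjusted p = 0.891 with an estimated correlation). Its mean deviation was 0.97 on intestine replicate 1 and 0.14 on intestine replicate 2. Intestinal epithelium genes fell in 5 of 15 cases, 5 adjusted over the list alone, including Fabp2 (-2.12), Fabp1 (-1.82) and Apob (-1.62), which handle lipids in enterocytes, and Vil1 (-1.22); the fifth, Tff3 (-0.53), was chosen after its values were seen (adjusted p = 0.0277 by camera, and adjusted p = 0.842 with an estimated correlation). That call ended without intestine replicate 2 (adjusted p = 0.0827). Macrophage and leukocyte genes had a median of -1.02 with 0 of 18 past the threshold by limma, 0 adjusted over the list alone, and the list stood lower (adjusted p = 0.000449 by camera, and adjusted p = 0.891 with an estimated correlation). Of the 17 genes of enteric neurons and glia, 3 fell, namely Erbb3 (-1.74), Ednrb (-2.40) and Sox10 (-1.09), and Gap43 rose (0.69). The list median was 0.023 while camera pointed down (adjusted p = 0.887).

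The smooth muscle contractile list held 5 genes higher in stomach, 3 lower and 15 not past the threshold, with the same counts adjusted over the list alone. Myocd, a coactivator of smooth muscle genes, was higher by 0.90 (SE 0.07, adjusted p = 0.00359), with Lmod1 (0.44), Cnn1 (0.34), Pdlim3 (0.81) and Smtn (0.31). Synpo2 (-0.89), Kcnmb1 (-0.66) and Ppp1r14a (-1.13) were lower. Camera gave no call for the list (adjusted p = 0.790). Lmod1, Cnn1, Pdlim3 and Smtn were chosen after their values were seen, as were Acta2, Tagln and Actg2, abundant genes of the contractile apparatus. These read 14.61, 14.22 and 13.75 in stomach and 14.56, 14.24 and 13.77 in intestine, and none of the differences passed (adjusted p from 0.561 to 0.844). Acta2 lay near the top of the array range, whose maximum was 14.7.

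Hox genes of paralog groups 6 to 13 moved both ways, with 3 higher in stomach (Hoxa7 0.79, Hoxa9 1.65, Hoxb9 0.75) and 2 lower of 19 (Hoxc8, and Hoxc9, -0.52, chosen after its values were seen); the list median was 0.030 although camera pointed down (adjusted p = 0.934). Of the 14 intestine mesenchyme regulators 4 rose and 5 fell, the latter with Tbx3 (-1.68), and the list gave no call (adjusted p = 0.808). The remaining lists gave no camera call in this comparison. Their adjusted p was 0.981 for Hox paralogs 1 to 5, 0.836 for secreted Wnt antagonists, 0.934 for Wnt targets, 0.981 for the Hedgehog response, 0.164 for BMP signalling and 0.229 for cartilage and tendon. It was 0.981 for interstitial cells of Cajal, 0.934 for mesothelium, 0.0561 for endothelium, 0.887 for erythroid cells, 0.229 for pancreas and 0.934 for liver. For skeletal muscle it was 0.836, for immediate early genes 0.790, for glycolysis and hypoxia 0.934 and for the interferon response 0.229. Skeletal muscle had a median of 0.060 and a mean of -0.048, liver 0.024 and -0.13, and immediate early genes -0.11 and 0.0065. Endothelium passed without stomach replicate 2 (adjusted p = 0.0184) and without intestine replicate 1 (adjusted p = 0.00477), and without the latter so did immediate early genes (adjusted p = 0.0247) and the interferon response (adjusted p = 0.00136). BMP signalling passed as lower with the filter on dim genes (adjusted p = 0.0481).

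In all, 1098 genes were higher and 1002 lower in stomach, 16.9% of those tested, with 110 and 166 at an absolute log2 difference of 1 or more. The arrays of the groups did not overlap for 64.1% of genes, where chance gives 33.3%. The counts were 590 higher and 633 lower without intestine replicate 1, 657 higher and 744 lower without intestine replicate 2, 226 and 162 without stomach replicate 1, and 143 and 138 without stomach replicate 2. Of the 86 named genes past the threshold, 40 stayed past it in all 6 such fits and 46 lost their call in at least 1, with no change of sign.

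The comparison of Barx1 intestine with intestine asks what changes with ectopic BARX1 in the cultured intestine cells, mesenchyme and other cell types together. Isl1 rose from 5.18 ± 0.17 to 9.74 ± 0.02 (SD, n = 2 each; difference 4.56, SE 0.10, adjusted p = 0.000207). Fap rose by 3.25 (SE 0.20), the vasopressin receptor gene Avpr1a by 2.78 (SE 0.09), Six2 by 2.22 (SE 0.09) and Ccn3, a matricellular protein gene, by 2.06 (SE 0.11). Among genes that fell, Itih5 changed by -4.65 (SE 0.32), P2ry14 by -2.93 (SE 0.07), Sptssb, a subunit of serine palmitoyltransferase, by -2.76, Mmp10 by -2.64, Erbb3, a neuregulin receptor of glial precursors, by -2.60 and the matrix gene Postn by -2.48. These 11 genes and Barx1 were the 12 of 57 named genes past the threshold that stayed past it in all 6 fits leaving out 1 array, and the other 45 lost their call in at least 1 of them, with no change of sign. Leaving out either stomach array gave the same fit for this comparison, so 1 fit counts 2 times among the 6.

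Of the stomach and pylorus regulators 4 of 14 rose, namely Barx1, Isl1, Six2 and Gata3 (1.74), and Grem1, a secreted BMP antagonist, fell (-1.36). Adjusted over the list alone, 8 rose and 1 fell (adjusted p = 0.000656 by camera, and adjusted p = 0.689 with an estimated correlation). Barx1 is the gene that the model expresses, so its rise was set by the design. It is part of these counts and of the list test, which was not run without it. Pitx1 rose by 2.36 and Mgp by 2.02; Pitx1 lost its call without either Barx1 intestine array, and Mgp in 5 of the 6 fits. Hox genes of paralog groups 6 to 13 had a median of 0.19, with 4 of 19 members higher and 0 lower, 6 adjusted over the list alone: Hoxa9 (1.93), Hoxb9 (1.14), Hoxd8 (0.88) and Hoxa7 (0.48) (adjusted p = 0.00113 by camera, and adjusted p = 0.689 with an estimated correlation). Hoxa9, Hoxb9 and Hoxd8 each lost their call in 4 of the 6 fits without 1 array, and Hoxa7 in all 6. Cell cycle genes had 4 of 25 higher, Bub1 (0.48), Birc5 (0.44), Ccna2 (0.35) and Plk1 (0.41), and 17 adjusted over the list alone (adjusted p = 6.76e-07 by camera, and adjusted p = 0.689 with an estimated correlation).

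Macrophage and leukocyte genes were lower, with a median of -1.84 over 18 genes. The 5 past the threshold were the complement genes C1qa (-2.53) and C1qc (-2.34), the Fc receptor gene Fcgr3 (-2.49), Coro1a (-1.84) and the chemokine receptor gene Cx3cr1 (-1.66), and 15 passed when adjusted over the list alone (adjusted p = 1.86e-09 by camera, and adjusted p = 0.689 with an estimated correlation). C1qc was chosen after its values were seen. Per array, the mean deviation of the list was 0.42 and 1.38 in intestine, and -1.26 and -0.37 in Barx1 intestine, replicates 1 and 2. The interferon list was lower as well, with Gbp2 (-1.02) as the 1 gene of 14 past the threshold and 3 adjusted over the list alone (adjusted p = 0.000280 by camera, and adjusted p = 0.689 with an estimated correlation). The endoderm epithelium list had a median of -0.74, with Spint1 (-1.64) as the 1 gene of 22 past the threshold and 2 adjusted over the list alone (adjusted p = 0.00386 by camera, and adjusted p = 0.689 with an estimated correlation); the call ended without intestine replicate 1 (adjusted p = 0.282) and without Barx1 intestine replicate 2 (adjusted p = 0.192). Of enteric neuron and glia genes 3 of 17 fell, Ednrb (-3.17), Erbb3 and Sox10 (-1.58), and the list gave no call (adjusted p = 0.210), but passed without intestine replicate 2 (adjusted p = 0.0198).

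Of 23 smooth muscle contractile genes, 0 were higher by limma and 2 fell, Kcnmb1 (-0.78) and Ppp1r14a (-0.76), with 1 higher and 4 lower adjusted over the list alone. The list median was near 0, at -0.021 (quartiles -0.43 to 0.016), while the list stood lower (adjusted p = 0.0136 by camera, and adjusted p = 0.689 with an estimated correlation). That call ended without Barx1 intestine replicate 1 (adjusted p = 0.113). Myocd read 6.37 ± 0.05 in Barx1 intestine and 6.37 ± 0.01 in intestine. Acta2 and Tagln, chosen after their values were seen, differed by -0.00099 and 0.024 (adjusted p = 0.994 and 0.838). Extracellular matrix genes had Bgn higher (0.64) and Postn, Thbs2 (-1.60) and Fbln2 (-0.60) lower of 25, with 3 higher and 5 lower adjusted over the list alone (adjusted p = 0.0223 by camera, and adjusted p = 0.689 with an estimated correlation); the call ended without intestine replicate 2 (adjusted p = 0.126) and without Barx1 intestine replicate 1 (adjusted p = 0.477). Bmp4 fell by 1.03 on the log2 scale, and Foxf2, of the Hedgehog response list, was lower (-0.69). Of the 14 intestine mesenchyme regulators 4 were higher, Nr2f1 (1.25) and the Hox genes Hoxa9, Hoxb9 and Hoxd8 given above, and 2 were lower, Tbx3 (-1.18) and Hlx (-1.18). Nr2f1, Hoxa9 and Hoxb9 were also called higher in stomach than in intestine (3.22, 1.65 and 0.75), and Tbx3 and Hlx lower (-1.68 and -0.78). Hoxd8 differed there by -0.38 without a call.

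No camera call was made for the other lists. The adjusted p was 0.263 for intestine mesenchyme regulators, 0.552 for Hox paralogs 1 to 5, 0.949 for secreted Wnt antagonists (median 0.019, camera pointing down), 0.548 for Wnt targets and 0.306 for the Hedgehog response. For BMP signalling it was 0.387, with a median of 0.16 and a mean of 0.0028. It was 0.548 for cartilage and tendon, 0.548 for interstitial cells of Cajal, 0.552 for intestinal epithelium, 0.267 for mesothelium, 0.0981 for endothelium and 0.311 for erythroid cells. Spleen primordium (0.387), pancreas (0.552), liver (0.949) and skeletal muscle (0.949) gave no call, nor did immediate early genes (0.117) and glycolysis and hypoxia (0.198), all given as adjusted p. Without intestine replicate 1 the last 2 lists passed (adjusted p = 1.6e-05 and 0.000169), as did the endothelium list (adjusted p = 0.00839), and without Barx1 intestine replicate 1 the immediate early list passed (adjusted p = 0.0322), as it did with the filter on dim genes (adjusted p = 0.0295). Skeletal muscle had a median of 0.026 and a mean of -0.038, and liver 0.023 and -0.015. The sex-linked genes, of which 4 were measured, were not tested as a list. The Y-linked genes Eif2s3y, Kdm5d and Uty differed by -1.54, -1.25 and -1.39 (adjusted p = 0.0966, 0.0657 and 0.0672), and Xist, expressed from the inactive X, by 1.84 (adjusted p = 0.139). None of the 4 passed the threshold, but for each of them both Barx1 intestine arrays lay on the same side of both intestine arrays, in the direction of more female cells. The labels used here do not give the sex of the embryos, so a different mix of sexes in the groups of this comparison is not excluded.

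In all, 230 genes were higher and 263 lower in Barx1 intestine, 3.98% of those tested, with 38 and 91 at an absolute log2 difference of 1 or more. The arrays did not overlap for 52.4% of genes, where chance gives 33.3%. The counts were 137 higher and 329 lower without intestine replicate 1, 50 and 105 without intestine replicate 2, 24 and 29 without Barx1 intestine replicate 1, 27 and 58 without Barx1 intestine replicate 2, and 19 and 31 without either stomach array or in a fit of these 2 groups alone. Centring each array on its median gave 354 higher and 274 lower.

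The overlap of both comparisons asks whether the Barx1 intestine moved toward the stomach. Of the genes called in each, 182 were higher in both and 186 lower in both, 368 in all, and 3 went opposite ways. Those higher in both included Isl1, Fap, Pitx1, Six2, Mgp, Avpr1a and Barx1, which the model itself expresses. Those lower in both included Itih5, P2ry14, Mmp10 and, from the enteric neuron and glia list, Ednrb. Because both comparisons share the intestine arrays, part of any overlap arises by chance, and part of the excess in the values that use both intestine arrays in both comparisons may come from the shared controls. At an unadjusted p under 0.05 in both, 1800 genes had the same direction, against a mean of 156 in 100 simulations of unchanged groups sharing those arrays, and 71.6% of all genes had the same sign, against 66.7% simulated. The simulated groups held no differences, whereas 4176 and 2924 genes reached that unadjusted p by limma in the real comparisons. Unrelated changes in that many genes would share more than 156, so the excess over 156 overstates the overlap. Independent lists of the called sizes would share 20.4 higher and 21.3 lower. The covariance of the differences across genes was 0.0871, against a simulated mean of 0.00661 (highest 0.00746) and 0.00964 computed from the residual variance, a difference from the simulated mean of 0.0805. With each intestine array used in 1 of the differences, the covariance was 0.0636 and 0.0838, each part holding 1 array. Across genes, which are not independent replicates, the correlation was 0.680 (Spearman 0.597), against a simulated highest of 0.539 with shared arrays, and 0.416 and 0.647 with the intestine arrays split. The same-direction count was 34 without stomach replicate 2, 37 without stomach replicate 1, 49 without Barx1 intestine replicate 1, 69 without Barx1 intestine replicate 2, 127 without intestine replicate 2 and 335 without intestine replicate 1.

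**Figure D2:**
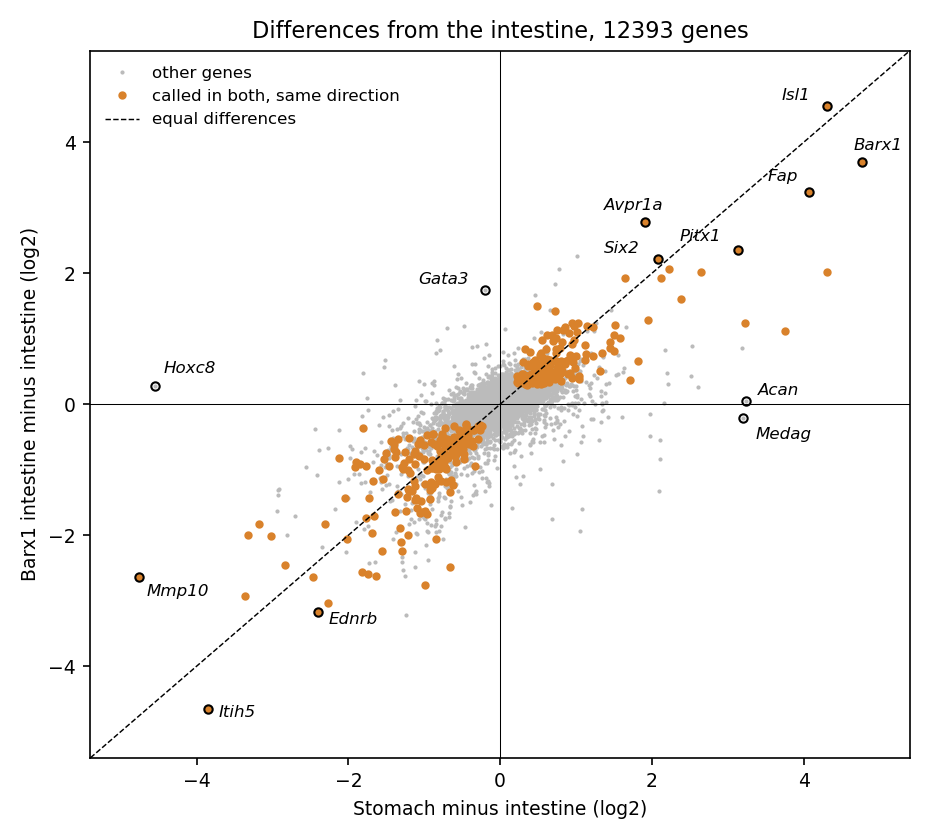
Each point is 1 of 12393 genes, with the log2 difference of stomach from intestine on the horizontal axis and that of Barx1 intestine from intestine on the vertical axis, each from 2 arrays per group. Orange points are the 368 genes called in both in the same direction; Isl1 lies near the dashed line of equal differences while Acan, Medag and Hoxc8 lie near 0 on the vertical axis.

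Most stomach genes were not called in the Barx1 intestine. Of the 1098 genes higher in stomach, 16.6% were also called higher there, and of the 1002 lower genes 18.6% were called lower. A gene without a call is not shown to be unchanged, and these shares depend on the threshold. In the other direction, 79.1% of the genes that rose in Barx1 intestine were higher in stomach, and 70.7% of those that fell were lower in stomach. Of all 12393 genes, 1098 were called higher and 1002 lower in stomach. Both comparisons use the same intestine arrays, which can raise the shares given here.

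The comparison of Barx1 intestine with stomach shows what still separated them. Hoxc8 was higher in Barx1 intestine (8.62 ± 0.22) than in stomach (3.78 ± 0.16; SD, n = 2 each; measured difference 4.84, SE 0.17, adjusted p = 0.00325), where the stomach level lay below the lower quartile of its arrays (4.76 and 4.75) and the difference is a lower bound. Hoxc8 in Barx1 intestine differed from intestine by 0.29 (adjusted p = 0.379). Aspn (-3.42), Medag (-3.41), Acan (-3.19, SE 0.15) and Prrx1 (-2.64) were lower than in stomach, as were Col1a2 (-2.46), a chain of type I collagen, Nr2f1 (-1.97) and Tlx1 (-1.33). Isl1 differed by 0.24 and did not pass (adjusted p = 0.209). Gata3 (1.94), Mmp10 (2.13), Rgs4 (2.11) and Car3 (2.29) were higher than in stomach.

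Extracellular matrix genes fell in 12 of 25 cases, 14 adjusted over the list alone, with Lox (-1.10) and Thbs2 (-2.68) beside Col1a2 (adjusted p = 8.49e-09 by camera, and adjusted p = 0.60 with an estimated correlation). Smooth muscle genes had 4 lower and 1 higher of 23, with 7 and 1 adjusted over the list alone and a list median of -0.094. Pdlim3 (-1.43), Des (-1.16), Hspb7 (-0.99) and Myocd (-0.89) were lower and Synpo2 (0.60), chosen after its values were seen, was higher (adjusted p = 0.00841 by camera, and adjusted p = 0.60 with an estimated correlation). The smooth muscle call ended without Barx1 intestine replicate 1 (adjusted p = 0.107). Cell cycle genes fell in 6 of 25 cases, 14 adjusted over the list alone, among them Cenpf (-0.52) and Mki67 (-0.47) (adjusted p = 3.03e-05 by camera, and adjusted p = 0.503 with an estimated correlation). The spleen list had Tlx1 and Nr2f2 (-0.92) lower of 7, 4 adjusted over the list alone (adjusted p = 0.000667 by camera, and adjusted p = 0.503 with an estimated correlation), and the cartilage and tendon list had Acan lower of 13, 2 adjusted over the list alone (adjusted p = 0.00706 by camera, and adjusted p = 0.503 with an estimated correlation).

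Hox genes of groups 6 to 13 had 4 of 19 higher, Hoxc8, Hoxd8 (1.25), Hoxb6 (0.81) and Hoxc9 (0.71), with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00706 by camera, and adjusted p = 0.586 with an estimated correlation). That call ended without Barx1 intestine replicate 1 (adjusted p = 0.0555) and with the filter on dim genes (adjusted p = 0.0525). BMP signalling genes had 3 higher, Id4 (0.89), Nog (0.78) and Smad7 (0.67), and 2 lower, Bmp4 (-0.78) and Bambi (-0.37, chosen after its values were seen), of 17, with 7 and 3 adjusted over the list alone (adjusted p = 0.0333 by camera, and adjusted p = 0.503 with an estimated correlation); the call ended without stomach replicate 2 (adjusted p = 0.0544), without Barx1 intestine replicate 2 (adjusted p = 0.0984) and with the filter on dim genes (adjusted p = 0.226). Intestinal epithelium genes had Fabp2 (1.72) and Apoa4 (1.81) higher of 15, 6 adjusted over the list alone (adjusted p = 0.0196 by camera, and adjusted p = 0.648 with an estimated correlation), and leukocyte genes had a median of -0.87 with 0 of 18 past the threshold by limma (adjusted p = 0.00412 by camera, and adjusted p = 0.678 with an estimated correlation). Without Barx1 intestine replicate 1 both calls ended (adjusted p = 0.120 and 0.317). Stomach and pylorus regulators, not called here (adjusted p = 0.0861), passed as lower without Barx1 intestine replicate 2 (adjusted p = 0.0114), without stomach replicate 2 (adjusted p = 0.0430) and with the filter (adjusted p = 0.0331). Without stomach replicate 2, enteric neurons and glia passed as lower (median -0.36) and endoderm epithelium as higher (median 0.50). Enteric neurons and glia also passed as lower with the filter (adjusted p = 0.0446 by camera). The interferon response passed as lower without stomach replicate 1 (median -0.17) or either intestine array (median -0.13).

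In all, 317 genes were higher and 327 lower in Barx1 intestine than in stomach, 5.20% of those tested, and the arrays did not overlap for 58.0% of genes, where chance gives 33.3%. Of the 1098 stomach genes 244 were still lower and of the 1002 intestine genes 243 were still higher than in stomach. The counts were 3 higher and 9 lower without stomach replicate 1, 3 and 2 without Barx1 intestine replicate 1, and 33 and 80 without Barx1 intestine replicate 2. Without stomach replicate 2 limma called 0 and 0 genes, with 1001 higher and 905 lower at an unadjusted p under 0.05, so that none of the 59 named genes past the threshold passed in all 6 fits.

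**Figure D3:**
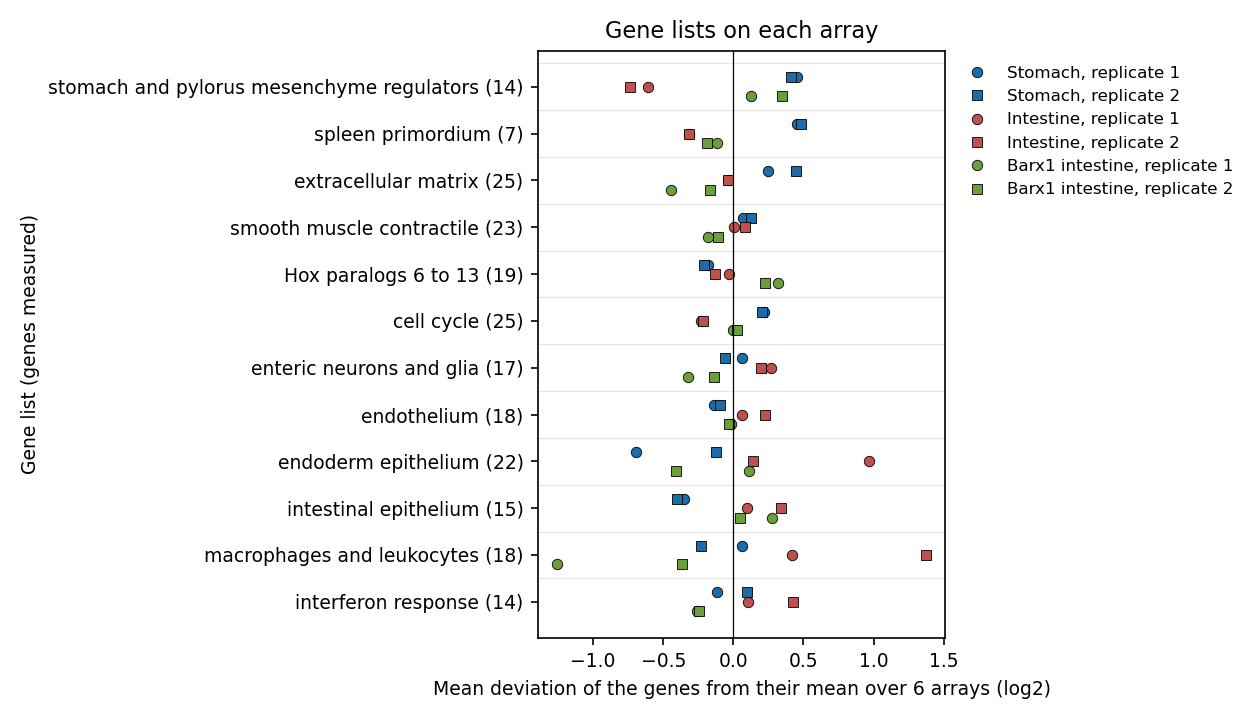
Mean log2 deviation of 12 gene lists on each of the 6 arrays, each gene first centred on its mean over the arrays. Points are single arrays, 2 per group; the leukocyte list reads 0.42 and 1.38 on the intestine arrays and -1.26 and -0.37 on the Barx1 intestine arrays.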

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

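Of the tests in this part, the split of the intestine arrays was planned and the others were chosen only after the results were seen. Probe sets without a single gene name lay outside the gene comparisons, and some of them carried signal: of 2246 such probe sets, 14 were higher and 25 lower in Barx1 intestine than in intestine by limma. The largest log2 difference was 1.83 among the higher (adjusted p = 0.00186) and -3.98 among the lower (adjusted p = 0.00891).

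For the movement of the Barx1 intestine toward the stomach, shared intestine arrays alone are argued against by the covariance of 0.0636 that remained when no intestine array entered both differences, above the highest simulated value of 0.00746. A loss of epithelial and leukocyte cells beside the mesenchyme would raise mesenchymal genes alike. The genes higher in both comparisons, picked because they passed, had a median of 0.51. Extracellular matrix and smooth muscle genes had a median of -0.12 (quartiles -0.46 to 0.03, 48 genes), so they did not rise as a set. Some of them were themselves called lower in Barx1 intestine, such as Postn and Kcnmb1, and Bgn was called higher. A loss of those cells is therefore not decided for the higher genes. For the genes lower in both, the median went from -0.85 to -0.54 once the epithelial and leukocyte list means entered the fit (quartiles -1.36 to -0.06, 146 of 186 with the same sign), so a loss of those cells and an effect on the mesenchyme cannot be told apart for them, with 1 residual degree of freedom left. In that fit the median of the higher genes was 0.61 where limma called 0 genes, with 269 higher and 266 lower at an unadjusted p under 0.05. An effect of BARX1 on part of the stomach program may account for the higher genes, as a hypothesis beside a change of cell mix. Only these explanations were tested, and a different mix of sexes or a different share of enteric neurons and glia was not.

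The second pattern is the lower level of leukocyte genes in Barx1 intestine. A single intestine array rich in leukocytes is argued against as the whole cause, since the median was -1.35 against intestine replicate 1 alone (quartiles -1.49 to -1.14, 16 of 18 genes below 0) and -1.84 against both arrays. A smaller share of leukocytes in these cultures may account for the rest but stays open: it would lower every leukocyte gene, and 17 of 18 had a difference below 0 (quartiles -1.98 to -1.68). Cd14 differed by 0.51 and Lyz2, the brightest of the list in intestine, by -0.20 (adjusted p = 0.421 and 0.834), against -1.96 for Ctss, so a smaller share and a change within the leukocytes cannot be told apart. All 18 genes lay above the median brightness in intestine and 0 stand in another list; whether embryos, dissections or genotypes differed in this was not tested.

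The third pattern concerns 4 of 19 Hox genes of paralog groups 6 to 13 that were called higher in Barx1 intestine, each losing its call in 4 or more of the 6 fits without 1 array, in a list that camera called at the preset correlation but not with an estimated one (adjusted p = 0.689). Fewer epithelial and leukocyte cells beside the mesenchyme are not decided here either, since some matrix and smooth muscle genes were themselves called lower. The matrix and smooth muscle genes had the same median of -0.12, where the 4 called Hox genes, picked because they passed, had 1.01. All 19 genes of the list had a median of 0.19 (quartiles 0.097 to 0.40). A more caudal stretch of intestine in the dissection remains open: the 5 Hox genes of these groups above the median brightness had a median of 0.48, with 3 of the 5 past the threshold and all 5 differences above 0, which such a stretch could give, and the labels used here do not give the stretch taken. Brightness was the mean over all arrays, so a rise itself could bring a gene in. Hoxb9 entered although it read 6.50 in intestine, and Hoxc8, at 8.33 in intestine, was left out. Hoxa9, Hoxb9 and Hoxa7 were also called higher in stomach than in intestine (1.65, 0.75 and 0.79), while Hoxd8 differed by -0.38 (adjusted p = 0.0523), so a caudal stretch and an effect of BARX1 cannot be told apart for these genes. With the list means in the fit the median of the 4 called genes was 0.79, with 3 of 4 above 0, and the calls ended with 1 residual degree of freedom.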

How the results depend on the processing

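The crossed replicate numbers and the list means as covariates were chosen after seeing the data; the other alternatives were fixed beforehand. Because the values are log2, the alternative for linear values was not run. The difference of Barx1 between Barx1 intestine and intestine kept its direction and call in every alternative except the covariates, and the second quantile normalisation kept every count within 1.5 times. For stomach against intestine, Barx1 intestine against intestine and Barx1 intestine against stomach in turn, leaving out 1 array gave 143 to 901, 19 to 137 and 0 to 356 genes higher, and 138 to 791, 29 to 329 and 0 to 371 lower, 34 to 335 genes called in both, a covariance of 0.0852 to 0.110, a Barx1 difference of 3.59 to 3.80, and 6 to 10, 7 to 10 and 5 to 11 lists. Those fits hold 2 residual degrees of freedom in place of 3, and a group of 1 array is assumed to vary like the others. For each comparison, leaving out either array of the group not compared gave the same fit. An adjusted p under 0.1 gave 1710, 642 and 778 genes higher, 1600, 674 and 738 lower and 918 in both; requiring an absolute log2 difference of 1 gave 110, 38 and 47, 166, 91 and 76, and 67. In the comparison of Barx1 intestine with intestine, the filter on dim genes gave 477 higher, a variance trend 506 higher and 531 lower, median centring 354 higher, and the fit of 2 groups 19 higher and 31 lower with 46 in both. Against stomach the filter gave 688 higher and 554 lower and the trend 622 and 567, with 606 and 708 genes in both. The covariance was 0.0742 with the mean of all probe sets and 0.0636 with split controls. Lists passing were 0, 0 and 0 with an estimated correlation and 4 and 2 with fry in the comparisons with intestine. Apart from fewer arrays, and the thresholds themselves, the cause was not tested. Deviations of same-numbered arrays correlated at -0.216 (stomach with intestine), -0.0615 (stomach with Barx1 intestine) and 0.203 (intestine with Barx1 intestine). With 2 arrays per group these signs depend on the numbering, so a pairing of the samples is neither shown nor excluded. With the replicate block, 94 genes were higher and 173 lower in Barx1 intestine than in intestine, 141 and 196 against stomach, and 206 in both, and the endothelium list passed for stomach against intestine (adjusted p = 0.0473). With the stomach numbers crossed, 190 were higher and 193 lower against stomach. With the list means as covariates, which leave 1 residual degree of freedom, limma called 0 genes in each comparison and 0 in both, with 372 higher and 281 lower at an unadjusted p under 0.05 for stomach against intestine, and Barx1 differed by 4.01 (adjusted p = 1.00). The same fit reversed the sign of named genes, to Actc1 -0.18, Gja1 -0.38, Hoxc4 0.27, Ifit2 0.20, Kcnmb1 0.16, Plvap 0.32, Spon2 1.24 for stomach against intestine, and C1qa 0.20, Ccnd1 -0.032, Foxf2 0.30, Gbp2 0.49, Gja1 -0.41, Hoxb5 0.011, Hoxd8 -0.095, Igfbp5 0.49, Kcnmb1 0.20, Spon1 0.11, Thbs2 1.53 for Barx1 intestine against intestine. C1qa belongs to the leukocyte list whose mean was a covariate, so the fit itself removed much of its difference. None of the reversed genes passed in that fit, so their signs are not read as changes. Dim genes lie near the background of the arrays, where log2 differences are compressed.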

Other observations

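The counts and genes in this part were chosen only after the results were seen. Some genes left the range of both organs in the Barx1 intestine: 20 were higher than in stomach and in intestine, where independent lists would share 5.88, and 33 were lower than in both, where they would share 6.94. Both comparisons share the Barx1 intestine arrays, so part of this excess can come from them. At an unadjusted p under 0.05 in both, 323 genes were higher and 340 lower, against means of 78.9 and 78.5 in 100 simulations of unchanged groups that share those arrays. The simulated groups held no differences. In the real comparisons 1526 genes were higher and 1398 lower than in intestine at that p by limma, and 1527 and 1473 than in stomach. Unrelated changes in that many genes would share more than the simulated means, so the excess over those means is overstated. Sex-linked genes also lay outside the range of both organs: Xist lay higher, and Eif2s3y, Kdm5d and Uty lower, on both Barx1 intestine arrays than on any stomach or intestine array, with differences from stomach of 1.12, -1.43, -1.10 and -1.04 (adjusted p = 0.311, 0.105, 0.0785 and 0.113), none past the threshold. A different mix of sexes is therefore not excluded in either comparison. The higher genes, named after their values were seen apart from Avpr1a, Gata3 and Hoxd8, include the homeobox gene Dlx2 (1.20 against intestine and 1.68 against stomach) and Sema3a (0.86 and 0.62), which encodes a guidance cue for axons. Gata3, a zinc finger factor, differed by 1.74 and 1.94. The lower genes include Postn (-2.48 and -1.82), Bmp4 (-1.03 and -0.78), Erbb3 (-2.60 and -0.86) and, named after their values were seen, the growth factor gene Ptn (-1.22 and -1.48) and the neurotrophin receptor gene Ngfr (-1.34 and -0.68). Without stomach replicate 2 limma called 0 genes against stomach, with 1001 higher and 905 lower at an unadjusted p under 0.05, so none of these genes passed both tests there.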
